A study of Mus musculus with 144 samples.

How the data were processed

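Polyadenylated RNA of liver and BAT was measured by sequencing in 144 samples, 120 of liver and 24 of BAT, from mice of 5 feeding regimens aged 6 months. Per the labels, RNA integrity numbers were above 7.5, libraries had 13 PCR cycles, mice entered at 8 weeks of age, and 72 mice were used per feeding condition. Entry at 8 weeks and the 10 weeks of feeding in the file headers fall short of 6 months, and the labels do not explain the gap. Restricted mice received 10 pellets a day in deliveries of 6, 2 and 2 pellets 2 h apart. The labels give a 12 h light cycle, while the series text gives constant darkness during sampling, and times are read as circadian times.

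The deposited count tables hold raw counts per gene, and the deposited RPKM tables hold reads scaled to gene length and library size, per the file headers. Per the submitters' processing notes the authors used FastQC, cutadapt, STAR and featureCounts, and neither tool versions nor the genome build are given in the sources used here. Counts were used for every test, and RPKM only for checks and 2 alternatives. RPKM times gene length was a constant multiple of the deposited counts of the same library, at a relative tolerance of 1e-04, in 120 of 120 liver and 23 of 23 BAT libraries. The count tables list 21869 genes. Coordinates come from GENCODE vM21 on build mm10: of 11350 genes in the deposited liver RPKM table, 9307 had the same versioned identifier there. Of these, 9227 had the same exon length, but only 6577 the same chromosome, start and end. GC content was known for 99.9% of the genes tested in liver.

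BAT CR-day at 0 h had RPKM but no counts and is left out of the count tests. In the deposited BAT CR-day counts, 1 more column carried the name of the last time point, was identical to a liver CR-day column and was not used, so that 143 of 144 count columns were used. No 2 libraries were near duplicates. Library totals ran from 5830040 to 26649153 in liver and 6978002 to 11607273 in BAT. Mitochondrial transcripts made up on average 25.9% of reads in liver and 61.4% in BAT. The reads carry no molecular identifiers, so intervals on counts cover counting error only. Residual spread lay over 4 median absolute deviations above the median in 7 liver and 2 BAT libraries, which were kept in the main tests. Across regimens, residuals at the same time had a median correlation of 0.0146 with the same letter and 0.0619 with the other letter. No pairing was used. Pairs of regimens ran from -0.373 (AL with CR-day) to 0.182 (CR-day with CR-night) with the same letter. The model held no term for the letter, so pairing is not excluded.

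Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes passed filterByExpr by group, leaving 11926 in liver, 10966 in BAT and 12799 in the fit of both tissues, and libraries were scaled by TMM. Each tissue had 1 model with an intercept, a cosine and a sine of a 24 h period per group. Rhythmic genes, rhythm changes between 2 groups and mean levels over the day were tested with edgeR's quasi-likelihood F test, with Benjamini-Hochberg adjustment within each test and a threshold of 0.05. Liver levels were compared for each regimen against AL, CR against TR, day against night and their interaction, BAT levels for CR-day against AL, and a further contrast took the BAT response minus the liver response to CR-day. CPM are given as mean ± SD over libraries and log2 folds as fit ± SE.

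Peak times and amplitudes come from least squares on log2 CPM with a prior count of 2, where the amplitude runs from the mean to the peak in log2 units. Shifts are group minus reference, within 12 h either way. The clock shift is the median over core clock genes rhythmic in every group compared, with a 95% interval from 2000 bootstraps of whole-library residuals. The 37 gene lists, covering the clock, metabolism, stress, sex-biased liver genes and other cell types, were tested for levels with camera at a preset correlation of 0.01, and again with the correlation estimated, for lists with at least 5 tested members. Members past the threshold were counted with adjustment over all genes and over the list alone. Overlaps used Fisher's exact test for pairs of contrasts without a shared library. It counts genes as independent, so its p-values do not measure spread between libraries.

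Genes are named by a fixed rule. For each level comparison with AL, CR against TR and day against night, these are the 6 largest rises and 6 largest falls past the threshold with at least 5 CPM in the higher group and the same sign in both letters (liver) or days (BAT), read from the fit of all libraries, without predicted models and pseudogenes. The rule adds up to 4 members with the smallest p of each list described, every core clock gene, the 6 largest rhythm changes of each comparison, Ucp1 in BAT, and Cyp7a1, Pck1, Fasn and Fgf21 in liver. Some genes picked by the rule are not reported here. The rule has no part for the tissue difference or the interaction.

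The methods were tested on simulated data with known changes. These counts were drawn with the same dispersion for every gene and without differences between replicate letters. The false calls below therefore do not cover the differences between letters in the real libraries. The simulated GC trend used the same GC content as the correction. For CR-day against AL in liver, levels changed by 1.25, 1.5 and 2-fold were recovered in 38 of 67, 66 of 67 and 66 of 66 genes with 9 false calls among 11777 genes. A GC trend in 1 group gave 8088 false calls without and 13 with correction. Rhythms with a peak to trough of 1.25, 1.5 and 2-fold were recovered in 1, 15 and 64 genes, with 1 false call, and rhythm changes in 4, 36 and 66, with 10 false calls. In BAT the level recoveries were 4, 57 and 66 with 13 false calls, rhythms 0, 0 and 11 with 0 false calls, and rhythm changes 0, 9 and 55 with 2, so rhythms of up to 2-fold in BAT were mostly missed. A GC trend gave 5689 false calls in BAT without and 5 with correction. For the BAT minus liver response 5, 39 and 64 genes were recovered, with 9 false calls among 12715. A list of 20 genes changed 1.25-fold, among 37 lists in all, gave an adjusted p of 9.9e-15 by camera, and 0 of the unchanged lists were called. Genes were drawn independently and lists at random, so this does not cover correlation between members of the real lists.

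Alternatives fixed beforehand were DESeq2, relative log expression size factors, no filter, time as a factor of 6 clock times, each day alone, each letter alone, a block for the letter, a minimum fold of 1.5, periods of 23.5 and 24.5 h, and log2 RPKM with a pseudocount of 0.1. Alternatives added after the data were seen were a correction for GC content and gene length by a spline with 5 degrees of freedom per library, also for overlaps, an intercept per regimen and letter, sums over each regimen and letter, the comparison of AL letter B with CR-day letter A, limma on RPKM of all 24 BAT libraries, and leaving out distant libraries.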

Results

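Messenger RNA of liver and brown adipose tissue (BAT) was sequenced from male C57BL/6J mice held for 10 weeks on 1 of 5 feeding regimens and then sampled every 4 h, at 12 time points, in constant darkness. Food was unlimited at all hours (AL), unlimited for 6 h at the start of the light phase (TR-day) or of the dark phase (TR-night), or held to 70% of baseline intake and delivered within 6 h at the start of light (CR-day) or dark (CR-night). Liver gave 120 libraries, 24 per regimen, with replicate letters A and B at each time. BAT gave 12 AL libraries of letter A and 12 CR-day libraries of letter B, of which 11 had counts. Library totals ran from 5830040 to 26649153 reads in liver (median 10705000) and from 6978002 to 11607273 in BAT (median 9351400). The submitters call the letters biological replicates, but the labels do not say whether the letters were separate animals or were prepared in separate batches, nor whether the 2 tissues came from the same mice, so the p-values measure spread between these samples. The gene lists and the rule for naming genes were fixed before the data were examined.

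The clock comparison in liver asked how far the hour of feeding and the amount of food moved the phase of the core clock genes, with circadian time (CT) counted in hours. In CR-day liver all 15 core clock genes that were rhythmic in both groups peaked earlier than in AL liver, with a median shift of -10.8 h (95% interval -11.5 to -9.74 h). TR-day liver moved in the same direction in 15 of 15 genes, by -9.91 h (-10.9 to -8.47 h). Arntl, an activator of the clock (ENSMUSG00000055116.8, chromosome 7, 113207465 to 113314126, mm10), peaked at CT 22.6 ± 0.399 in AL, 12.0 ± 0.615 in CR-day and 12.7 ± 0.597 in TR-day liver (fit ± SE, n = 24 libraries per group). Its target Dbp (ENSMUSG00000059824.12, chromosome 7, 45705088 to 45710203) moved from CT 10.3 ± 0.363 to 0.411 ± 0.651 and 1.42 ± 0.669. Nr1d1, which encodes a repressor of Arntl, went from CT 7.70 ± 0.327 to 20.8 ± 0.624 under CR-day and 21.7 ± 0.603 under TR-day. Shifts are read within 12 h either way, so a peak more than 10 h earlier lies opposite to its old position on the daily cycle.

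Night feeding left the same genes near their AL times. The median shift was -1.09 h in CR-night liver (-1.66 to -0.471 h), with all 16 genes earlier, and -0.252 h in TR-night liver (-0.788 to 0.222 h), with 13 genes earlier and 4 later. Arntl peaked at CT 21.4 ± 0.302 in CR-night and 22.4 ± 0.331 in TR-night liver, and Per2 at CT 14.6 ± 0.317 and 15.4 ± 0.335 against 15.3 ± 0.468 in AL. Between day and night feeding the clock differed by -9.89 h under caloric restriction (-10.4 to -8.64 h) and by -9.69 h under time restriction alone (-10.6 to -8.17 h). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 18 of 19 core clock genes changed rhythm in CR-day and 17 of 19 in TR-day liver against AL (18 and 19 when adjusted over the list alone). In all, 3 did so in CR-night liver when adjusted over the list alone.

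**Figure D1:**
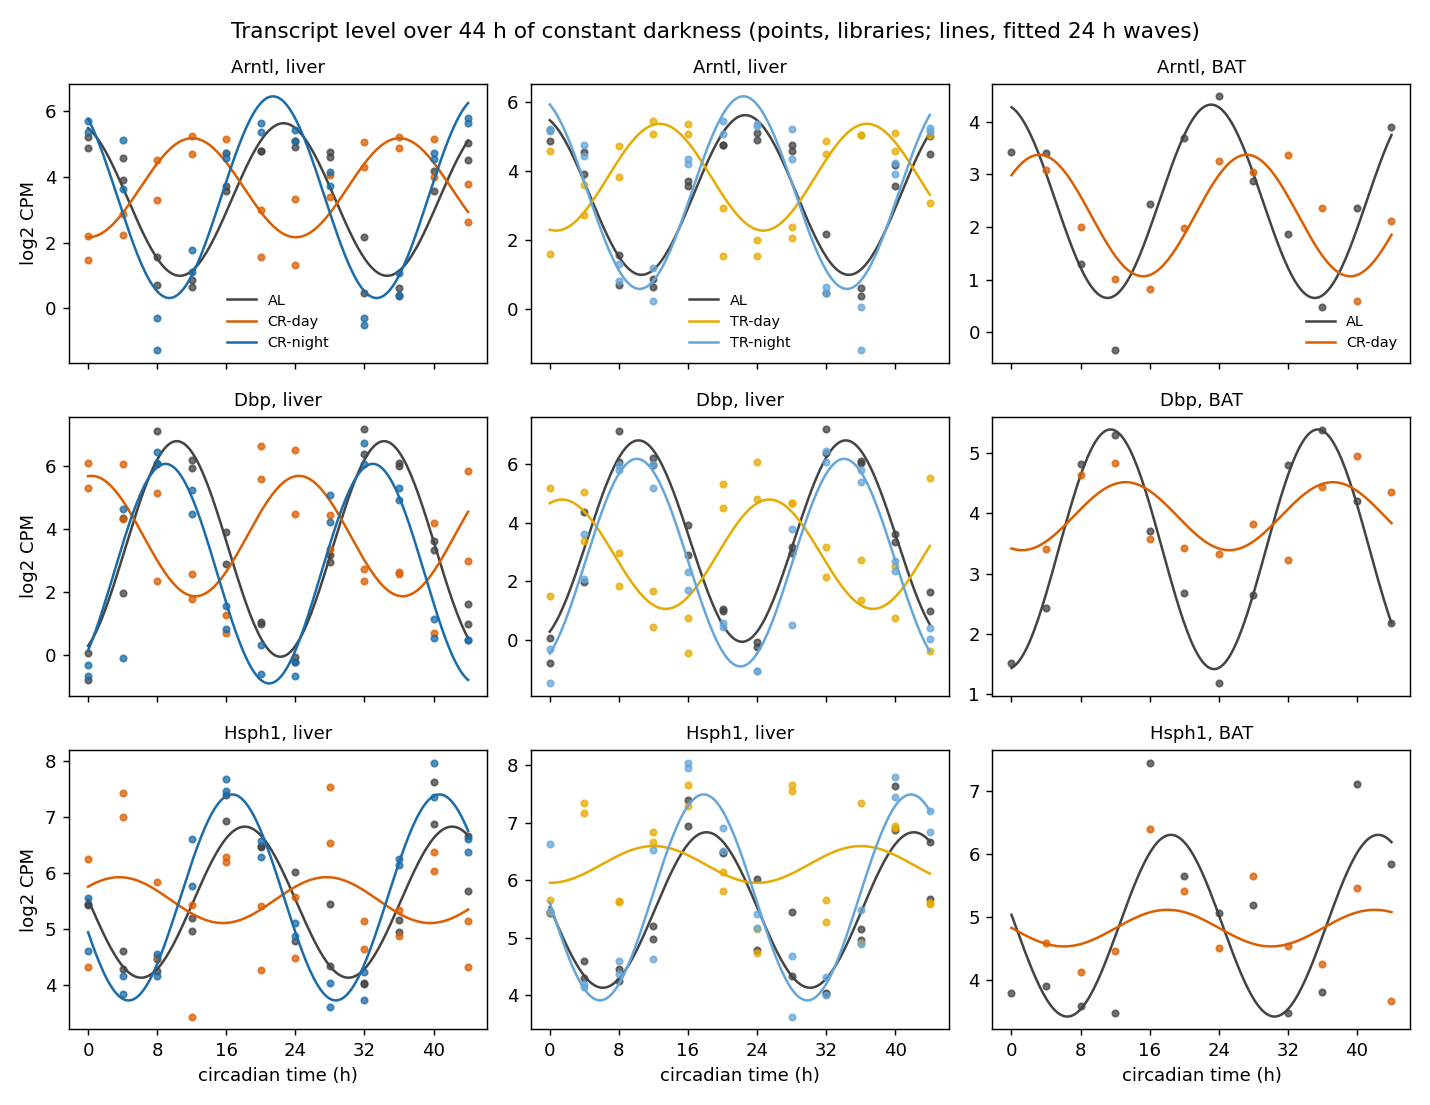
Log2 counts scaled to library size (CPM) of Arntl, Dbp and Hsph1 against circadian time in h, for liver under caloric restriction, liver under time restriction and BAT, each with its AL group; points are libraries and lines are fitted 24 h waves. The Dbp wave of liver moves from a peak at CT 10.3 in AL to 0.411 in CR-day, while in BAT its amplitude falls to 0.57 log2 units.

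The amplitude of the clock genes was compared across the same groups. The median amplitude of the core clock list was 1.57 log2 units in AL liver, 1.15 in CR-day, 0.76 in TR-day, 1.91 in CR-night and 2.00 in TR-night. The TR-day value includes 2 letter A libraries, at 0 and 44 h, whose clock genes read -8 and -6.25 h from the label. Per1 went from 2.05 ± 0.30 in AL (rhythm test, adjusted p = 3.5e-07) to 0.13 ± 0.30 in CR-day (adjusted p = 0.985) and 0.36 ± 0.30 in TR-day liver (adjusted p = 0.798). Its rhythm changed in both comparisons by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 1.4e-04 and 0.00170). Arntl had an amplitude of 2.32 ± 0.24 in AL, 1.505 ± 0.24 in CR-day and 3.07 ± 0.24 in CR-night liver, and Dbp 3.43 ± 0.33, 1.91 ± 0.33 and 3.49 ± 0.33.

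The same comparison in BAT asked whether CR-day feeding moves the clock of brown fat as it moves that of liver. Among the 8 core clock genes rhythmic in both BAT groups the median shift was 1.00 h (95% interval -1.68 to 3.62 h), with 3 genes earlier and 5 later. Single genes ran from -3.51 ± 1.20 h for Hlf to 9.60 ± 1.46 h for Bhlhe40. Arntl peaked 4.12 ± 0.946 h later, at CT 3.23 ± 0.814 against 23.1 ± 0.482, and Nfil3 5.61 ± 1.34 h later, while Per2 shifted by -3.14 ± 1.39 h (n = 11 CR-day and 12 AL libraries). The amplitude of Per2 went from 2.26 ± 0.21 to 0.58 ± 0.23 and that of Dbp from 1.99 ± 0.18 to 0.57 ± 0.20, with a changed rhythm by edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment (adjusted p = 1.2e-04 and 9.1e-04). Per3 went from an amplitude of 1.30 ± 0.15 to 0.27 ± 0.16 (adjusted p = 5.8e-04). Of 18 core clock genes, 14 were rhythmic in AL and 9 in CR-day BAT, and 10 changed rhythm (13 when adjusted over the list alone). With the libraries of day 1 alone the BAT median shift was -0.704 h, the opposite sign. GC and length correction gave 0.063 h (-2.29 to 2.94 h), with 4 genes earlier and 4 later.

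**Figure D2:**
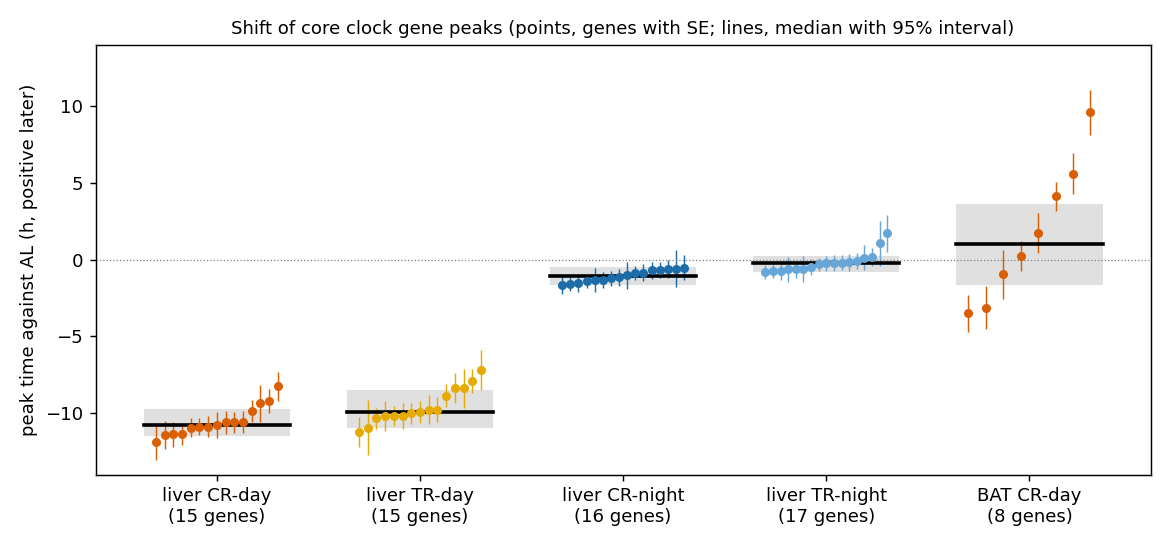
Peak time against AL in h for core clock genes rhythmic in both groups, in liver under CR-day, TR-day, CR-night and TR-night and in BAT under CR-day; points are genes with SE, lines are medians and grey bands their 95% intervals. Day-fed liver sits near -10.8 and -9.91 h, night-fed liver near -1.09 and -0.252 h, and BAT near 1.00 h with the widest spread.

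A direct comparison of the tissues asked whether the response to CR-day feeding itself differed. Over the 7 clock genes rhythmic in all 4 groups the BAT shift minus the liver shift was 12.3 h (95% interval 8.92 to 15.5 h), and the shifts of single genes had an SD of 4.32 h in BAT (2.92 to 6.15 h) against 0.898 h in liver (0.628 to 1.76 h). This difference of 2 medians is not folded onto the 24 h cycle and its interval passes 12 h, the largest distance on that cycle, so it does not say whether BAT moved earlier or later than liver. The rhythm response differed between tissues in 552 of 12799 genes by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, among them 13 of 19 core clock genes. Nfil3 (adjusted p = 8.1e-06), Tef (5.1e-05), Ciart (5.8e-05), Per3 (9.8e-05) and Nr1d1 (2.9e-04) passed, while Per2 (0.604) and Per1 (0.855) did not. Outside the clock the rhythm response differed for Ehhadh (adjusted p = 5.1e-11), Pdk4 (1.7e-08) and Acly (0.00143), while that of Pck1 did not pass (0.909).

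Rhythmic genes beyond the clock were counted to ask how much of the daily program of liver followed food. Of 11926 genes, 1479 were rhythmic in AL, 1950 in CR-day, 4211 in CR-night, 1843 in TR-day and 3148 in TR-night liver. With times permuted within the regimen 4 of 30 orders, the real one included, gave as many in CR-day (highest other 4872). With GC correction the counts were 2319, 2945, 5311, 2779 and 4352. Rhythms changed in 2613 genes in CR-day and 1944 in TR-day liver against AL, and day feeding differed from night feeding in 4055 genes under caloric restriction and 3077 under time restriction. Night feeding changed the rhythm of 3 genes (CR-night) and of 1 gene, Cyp2a4 (TR-night, adjusted p = 0.0261 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). As many rhythm changes came in 2 of 30 splits of the labels for CR-day, 2 for CR-day against CR-night, 4 for CR-night and 14 for TR-night, so chance is not excluded for these counts. Permuted times mixed the letters, which the real order balances over time, and 9059 genes differed between the letters of CR-day. The permutation therefore cannot decide whether chance gave the rhythmic genes of CR-day. Among 479 genes rhythmic in AL and CR-day with at least 1.5-fold peak to trough, 89.8% shifted by more than 6 h, against 72.2% of 432 genes in TR-day. In contrast, 81.5% of 992 genes in CR-night and 90.8% of 1003 in TR-night stayed within 2 h. The largest rhythm changes in CR-day liver included Dbp, Nr1d1, Per3, Pnpla3 and Elovl3, a fatty acid elongase whose peak went from CT 23.79 ± 0.660 to 12.0 ± 0.540. Those in TR-day liver included Dbp, Nr1d1 and the cell cycle inhibitor Cdkn1a. Mitochondrial transcripts mt-Co2 and mt-Co3, also among the largest between TR-day and TR-night, may share reads with near-identical nuclear copies and remain uncertain.

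Lipid synthesis genes peaked at different hours in day-fed and night-fed liver. Of 20 fatty acid synthesis genes, 4 were rhythmic in AL liver, 14 in CR-day, 13 in CR-night, 12 in TR-day and 16 in TR-night. Rhythm changed in 15 genes in CR-day and 11 in TR-day liver (15 and 13 when adjusted over the list alone). Pnpla3 peaked at CT 8.64 ± 0.537 in CR-day and 9.10 ± 0.582 in TR-day but at 19.8 ± 0.651 in CR-night and 20.5 ± 0.621 in TR-night liver. It had an amplitude of 3.30 ± 0.46 in CR-day against 1.49 ± 0.46 in AL (rhythm adjusted p = 0.166 in AL, quasi-likelihood test with Benjamini-Hochberg adjustment). Acly, which supplies acetyl-CoA, peaked at CT 9.39 ± 0.464 and Fasn at 8.96 ± 0.717 in CR-day liver, with changed rhythm for Acly (adjusted p = 7.2e-09). Cholesterol genes were rhythmic in 8 of 22 in AL, 12 in CR-day, 10 in TR-day, 13 in CR-night and 12 in TR-night liver. Lss peaked at CT 8.14 ± 0.641 and 7.83 ± 0.671 with day feeding against 21.5 ± 0.863 and 21.2 ± 0.829 with night feeding. The rhythm of 14 of 22 cholesterol genes changed in CR-day and 8 in TR-day liver (15 and 12 over the list alone).

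Fasting genes of liver followed with different distances. Cpt1a, the entry step of mitochondrial fatty acid oxidation, moved from CT 11.1 ± 0.596 in AL to 22.4 ± 0.554 in CR-day and 23.6 ± 0.730 in TR-day liver. Pck1 moved from CT 10.5 ± 0.991 to 18.0 ± 0.805 and 18.1 ± 0.759, shifts of 7.54 ± 1.28 and 7.61 ± 1.248 h, and Angptl4 shifted by 4.13 ± 1.31 and 4.44 ± 1.08 h. Pdk4 had an amplitude of 0.69 ± 0.22 in CR-day against 2.20 ± 0.22 in AL liver and a changed rhythm (adjusted p = 6.4e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Rhythm changed in 13 of 17 fasting and insulin response genes in CR-day and 11 in TR-day liver, and in 10 and 8 of 25 fatty acid oxidation genes. Rhythmic members of that oxidation list numbered 8 in AL, 6 in CR-day, 12 in CR-night, 4 in TR-day and 12 in TR-night liver.

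Heat shock genes changed their 24 h wave in day-fed liver. Of 17 members, 14 were rhythmic in AL, 15 in CR-night and 17 in TR-night liver, against 5 in CR-day and 3 in TR-day. Rhythm changed in 15 members in each day-fed group against AL (16 and 15 over the list alone). Hsph1 had an amplitude of 1.35 ± 0.22 in AL (rhythm adjusted p = 7.7e-07, quasi-likelihood test with Benjamini-Hochberg adjustment), 0.41 ± 0.22 in CR-day (adjusted p = 0.141) and 0.32 ± 0.22 in TR-day liver (0.587). Its rhythm changed in both (adjusted p = 9.8e-07 and 1.2e-04). In CR-night and TR-night liver Hsph1 reached 1.84 ± 0.22 and 1.79 ± 0.22. The median amplitude of the list was 0.66 in AL, 0.41 in CR-day, 0.31 in TR-day, 0.88 in CR-night and 0.89 in TR-night liver. In BAT it went from 0.71 in AL to 0.25 in CR-day.

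**Figure D3:**
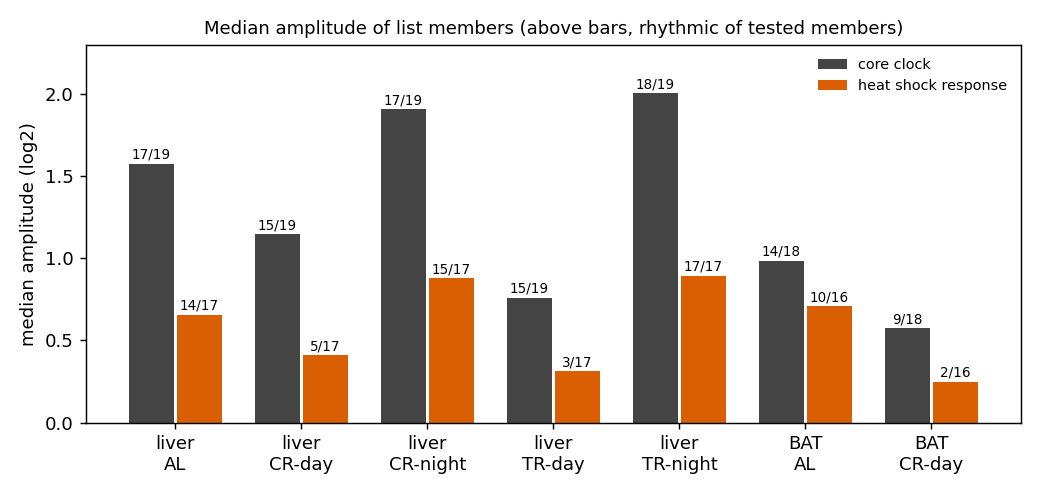
Median fitted amplitude in log2 units of the core clock and heat shock lists in the 5 liver and 2 BAT groups; bars are medians over list members, and the numbers above give rhythmic members of those tested. The heat shock bar goes from 0.88 in CR-night to 0.41 in CR-day liver with 15 and 5 of 17 members rhythmic, and the clock bar from 1.91 to 1.15 with 17 and 15 of 19.

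In BAT the same count asked which daily rhythms followed CR-day feeding. Of 10966 genes, 1148 were rhythmic in AL and 1660 in CR-day BAT, and 1323 changed rhythm by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among 291 genes rhythmic in both groups with at least 1.5-fold peak to trough, 59.5% shifted by more than 6 h and 17.9% by less than 2 h. Ehhadh, a peroxisomal oxidation enzyme, peaked at CT 8.97 ± 0.972 in AL and 21.1 ± 0.592 in CR-day BAT (adjusted p = 8.1e-06), Pck1 at 8.10 ± 0.937 and 21.7 ± 0.426, and Pdk4 at 7.54 ± 0.819 and 20.3 ± 0.429. Angptl4, an inhibitor of lipoprotein lipase, gained a rhythm with an amplitude of 2.33 ± 0.20 in CR-day against 0.19 ± 0.20 in AL BAT (adjusted p = 3.4e-06). Lep, which encodes the satiety hormone leptin, moved from CT 19.5 ± 0.987 to 6.91 ± 0.914, Mt2 from 11 ± 0.653 to 22.6 ± 1.10, Hephl1 from 21.0 ± 0.867 to 7.13 ± 0.467 and Hyls1 from 20.5 ± 0.444 to 6.42 ± 0.497. Cyp2e1 was also among the 6 largest changes, and whether it shares reads with other Cyp2 genes was not tested.

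Cholesterol genes changed rhythm in CR-day BAT. Of 21 members, 4 were rhythmic in AL and 16 in CR-day BAT, and 10 changed rhythm (15 when adjusted over the list alone). Insig1 peaked at CT 20.4 ± 0.978 in AL and 7.65 ± 0.693 in CR-day BAT, and Sqle at 0.828 ± 1.41 and 9.35 ± 0.555. Fatty acid synthesis had 5 of 20 rhythmic members in each group but 9 with changed rhythm (10 over the list alone), including Acly (adjusted p = 0.00311 by the quasi-likelihood test with Benjamini-Hochberg adjustment) and Pnpla3 (1.6e-05). Rhythm changed in 9 of 19 adipogenesis and adipokine genes and in 8 of 20 fatty acid oxidation genes. Heat shock members were rhythmic in 10 of 16 in AL and 2 of 16 in CR-day BAT, with 3 changed rhythms, and Hspa8 moved from CT 19.0 ± 0.466 to 7.29 ± 0.736.

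Mean levels in liver carried a structure by replicate letter that crosses the regimens. The main component of the 120 liver libraries held 43.4% of the variance, with mean scores of 76.9 in AL letter B and 71.6 in CR-day letter A (n = 12 each). The mean was 26.0 in AL letter A and -42.9 to -11.6 in the 7 other sets. Mitochondrial transcripts made up 13.3% and 13.7% of reads in those 2 sets, 22.8% in AL letter A and 27.1 to 32.1% in the others. The gene loadings followed GC content (Spearman's rho = 0.834 across genes). Between letters of the same regimen 6930 genes differed in AL and 9059 in CR-day, against 1583 in CR-night, 1790 in TR-day and 2522 in TR-night liver, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Genes of the Mup, Cyp2, Cyp3a, Cyp4a and Serpina1 families may share reads with close paralogs, which was not measured. Their values are uncertain in every comparison that follows. Shared reads named below, also for mitochondrial transcripts, mean this possibility. For many genes and lists the values within letters A and B are therefore given, and for each comparison the count from sums of each regimen and letter.

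**Figure D4:**
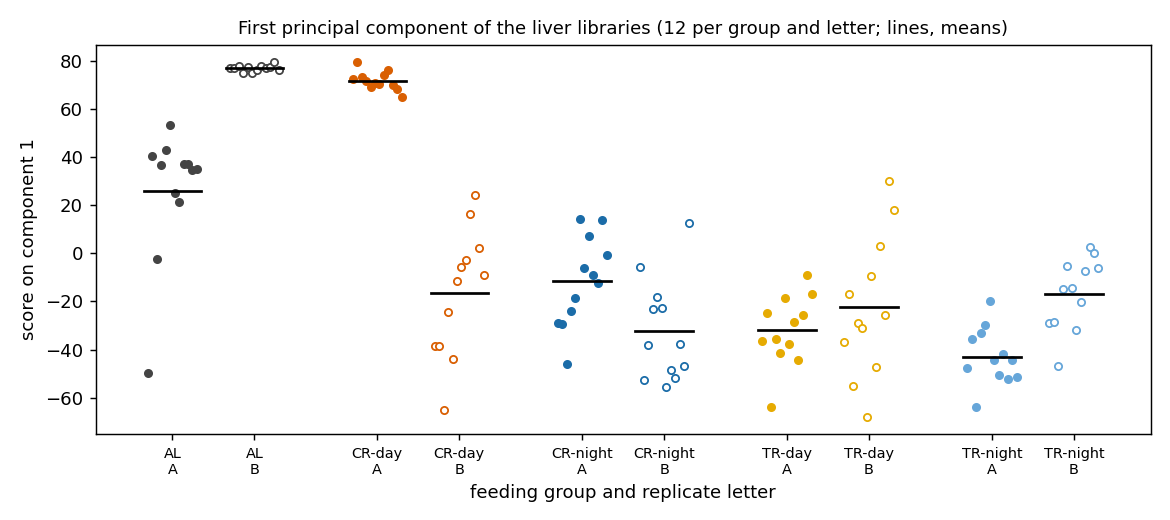
Score on the main component of liver for each library (vertical axis, no unit) by regimen and letter; points are libraries and lines are means of 12 libraries. AL letter B and CR-day letter A lie at 76.9 and 71.6, apart from every other set.

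CR-day against AL asked what eating less, in the light phase, does to liver gene levels averaged over the day. By edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 1500 genes rose and 832 fell among 11926. Of these 2332 calls, 2098 were called in the same direction within letter B alone, while within letter A alone 1212 were called again and 472 of them kept their direction. All 18 male-biased liver genes fell, with a median log2 fold of -1.47 (-1.63 and -1.44 within letters A and B, camera adjusted p = 6.5e-26, 0.00905 with an estimated correlation). Without distant libraries, of which 2 were CR-day libraries low in male-biased genes, all 18 fell with a median of -1.38. Selenbp2 (ENSMUSG00000068877.12, chromosome 3, 94693556 to 94704413) fell by 4.03 ± 0.35 log2 units, from 47.0 ± 44.7 to 2.68 ± 2.65 CPM (mean ± SD, adjusted p = 1.4e-17), and Serpina12 by 3.11 ± 0.27 (letters -3.26 and -2.94). Moxd1, which encodes a monooxygenase-like protein (ENSMUSG00000020000.7, chromosome 10, 24223517 to 24302790), dropped from 16.1 ± 22.9 to 0.0189 ± 0.0645 CPM (log2 -9.78 ± 0.98, letters -10.01 and -9.61). Mup17 (-4.36 ± 0.52), Mup11 (-3.88 ± 0.52), Mup14 (-3.85 ± 0.45), Mup20 (-1.73 ± 0.20), Serpina1e (-4.43 ± 0.38) and Cyp4a12b (-2.38 ± 0.30) fell as well, all of families with shared reads. Of 10 female-biased genes 7 rose and 1 fell, with a median of 1.60 (1.06 and 1.79 by letter, camera adjusted p = 3.9e-09, 0.0164 with an estimated correlation). Cyp2b9 rose by 7.92 ± 0.65, from 1.55 ± 5.54 to 127 ± 95.5 CPM.

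Fatty acid oxidation genes rose in the same comparison. Of 25 members 15 rose and the others did not pass, with a median of 0.28 (0.47 and 0.33 by letter, camera adjusted p = 7.8e-18, 0.00127 with an estimated correlation). Cyp4a14, a microsomal omega-hydroxylase, rose by 4.38 ± 0.36 log2 units, from 66.1 ± 97.9 to 1168 ± 384 CPM (letters 4.12 and 4.72). Cyp4a10 rose by 2.92 ± 0.22 (letters 2.72 and 3.15). Ehhadh rose by 0.96 ± 0.09 (letters 1.13 and 0.80, adjusted p = 8.1e-17 by the quasi-likelihood test with Benjamini-Hochberg adjustment) and Acadm by 0.59 ± 0.06. The peroxisomal genes Acot3 (2.52 ± 0.28) and Abcd2 (1.15 ± 0.17) rose as well, but they belong to the female-biased list and not to the oxidation list. Xenobiotic genes rose in 9 of 21 and fell in 1 (camera adjusted p = 1.7e-05, 0.0185 with an estimated correlation). Examples were Cyp2b10 (3.93 ± 0.52), Abcb1a (1.65 ± 0.21) and Cyp3a11 (1.53 ± 0.24, but 0.07 and 2.59 in letters A and B). Slc22a26 (4.10 ± 0.35) and Cyp2a22 (4.55 ± 0.44) were also among the 6 largest rises. Another, mt-Atp8 (7.56 ± 1.48), may share reads with neighbouring and nuclear copies.

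Lipid synthesis went the other way in part of its members. Of 20 fatty acid synthesis genes 7 fell (12 when adjusted over the list alone), with a median of -0.44 (-0.07 and -0.72 by letter, camera adjusted p = 6.5e-05, but 0.430 with an estimated correlation). Fads1 (-0.25 ± 0.06, letters -0.36 and -0.13) and Thrsp (-1.02 ± 0.27, letters -0.28 and -1.84) were examples. Fads2 (-0.60 ± 0.17) and Slc25a1 (-0.42 ± 0.11) passed as well but went opposite ways in the letters (0.17 and -1.66 for Fads2, 0.11 and -1.05 for Slc25a1). Fasn stood at -0.80 ± 0.33 (letters 0.51 and -2.60, adjusted p = 0.0704, quasi-likelihood test with Benjamini-Hochberg adjustment). Of 22 cholesterol genes 6 fell (7 over the list alone, camera adjusted p = 1.2e-04, 0.446 with an estimated correlation), including Fdps (-0.66 ± 0.18, letters -0.15 and -1.31) and Sqle (-0.49 ± 0.17, letters -0.61 and -0.36). Other members of this list did not fall in both letters. Dhcr7 stood at 0.38 when refitted without letter B and -1.81 without letter A, and Nsdhl at -0.68 and 6.9e-04. Of 17 fasting and insulin response genes 6 rose (8 over the list alone, camera adjusted p = 0.0361, 0.430 with an estimated correlation), including Lpin2 (0.39 ± 0.10, letters 0.34 and 0.43) and Insr (0.30 ± 0.08, but -0.07 and 0.67 in letters A and B). Values for Pck1 (0.21 ± 0.27), Cyp7a1 (0.16 ± 0.25) and Fgf21 (0.00 ± 0.35) did not pass. Endothelial markers rose in 6 of 13, fibroblast markers in 3 of 13 and mitochondrial transcripts in 4 of 13, hepatocyte markers fell in 4 of 12, autophagy genes in 3 of 16 and erythroid markers in 1 of 5. With correction for GC content and length 1025 genes rose and 872 fell. On sums of regimen and letter 26 genes passed, among them Moxd1 (adjusted p = 4.7e-04) and Cyp4a14 (0.00206).

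**Figure D5:**
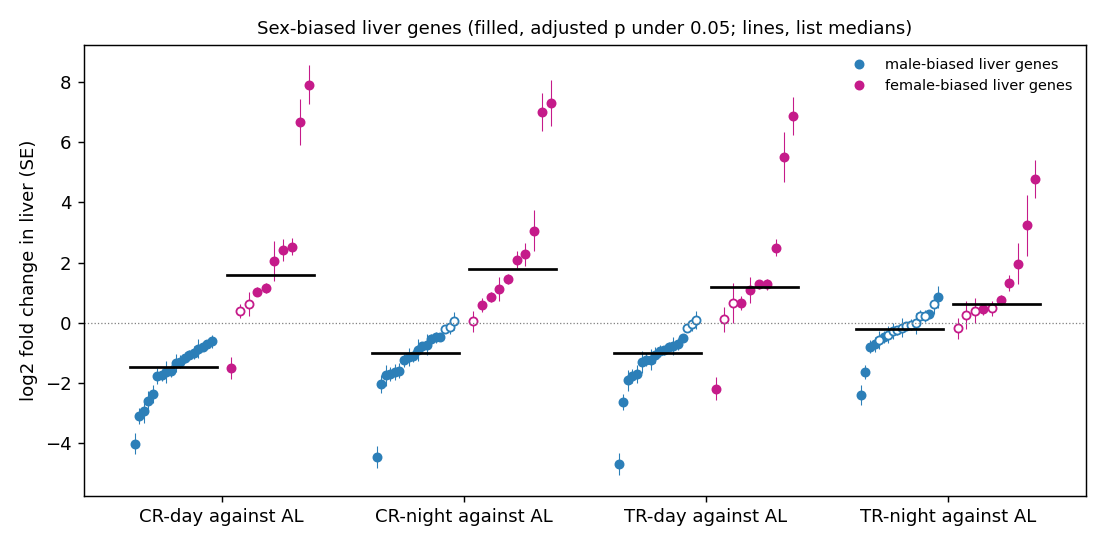
Log2 fold against AL with SE for male-biased and female-biased liver genes in CR-day, CR-night, TR-day and TR-night; points are genes, filled where the adjusted p is under 0.05, and lines are medians. Male-biased medians run at -1.47 in CR-day, -1.01 in CR-night, -1.01 in TR-day and -0.21 in TR-night.

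CR-night against AL asked the same of restricted food given in the normal eating phase. The quasi-likelihood test called 4544 genes higher and 4898 lower, and on sums of regimen and letter 20 passed. Cyp2b9 rose by 7.01 ± 0.64 log2 units (letters 9.49 and 5.84, n = 24 libraries per group), Cyp2a4 by 3.06 ± 0.69 and Cyp4a14 by 3.07 ± 0.34. Rises of mt-Atp8 (8.33 ± 1.51) and mt-Co2 (4.11 ± 1.12) are uncertain, as these transcripts may share reads. Moxd1 fell by 8.53 ± 0.93, Selenbp2 by 4.48 ± 0.37 (letters -3.70 and -5.55) and Bri3 by 2.69 ± 0.31, along with Mup17 (-5.32 ± 0.55), Mup11 (-3.31 ± 0.50) and Mup14 (-2.70 ± 0.42). Of 18 male-biased genes 15 fell (camera adjusted p = 0.0112, 0.991 with an estimated correlation), including Cyp2d9 (-1.71 ± 0.22). Of 10 female-biased genes 9 rose (adjusted p = 0.00785, 0.870 with an estimated correlation). Fasn fell by 1.70 ± 0.34 (adjusted p = 4.3e-06, quasi-likelihood test with Benjamini-Hochberg adjustment) and Fgf21 by 1.52 ± 0.41 (adjusted p = 4.9e-04). Cyp7a1 rose by 0.77 ± 0.25, or 0.11 with GC correction (adjusted p = 0.726). Pck1 stood at -0.18 ± 0.27 (adjusted p = 0.525). Mitochondrial transcripts rose in 11 of 13 (camera adjusted p = 0.00639, 0.870 with an estimated correlation). Macrophage markers such as C1qa (-1.91 ± 0.24) and H2-Ab1 (-1.57 ± 0.22) fell in 13 of 16 (0.991 with an estimated correlation).

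TR-day against AL asked what the hour of feeding does when food is unlimited within its window. The quasi-likelihood test called 4566 genes higher and 5018 lower, and on sums of regimen and letter 25 passed. Cyp2b9 rose by 6.88 ± 0.63 log2 units (letters 8.79 and 6.35), Cyp2a22 by 4.40 ± 0.44, Slc22a26 by 3.27 ± 0.35, Cyp4a14 by 4.25 ± 0.36 and, with shared reads, mt-Atp8 by 7.84 ± 1.49. Moxd1 had 1 read in 24 TR-day libraries against 16.1 ± 22.9 CPM in AL, a ratio of 3538 with a counting interval of 635 to 139760. Selenbp2 fell by 4.70 ± 0.38 (letters -4.85 and -4.56), Bri3 by 2.81 ± 0.31 and Serpina12 by 2.63 ± 0.27, along with Serpina1e (-4.50 ± 0.38), Mup7 (-2.83 ± 0.48) and Mup17 (-2.75 ± 0.48). Of 25 fatty acid oxidation genes 16 rose and 7 fell (camera adjusted p = 0.00587, 0.998 with an estimated correlation). Rises were 2.99 ± 0.22 for Cyp4a10, 2.11 ± 0.18 for Acot1 and 0.70 ± 0.06 for Acadm. Male-biased genes fell in 15 of 18 (camera adjusted p = 0.0284, 0.998 with an estimated correlation). Fasn stood at -1.73 ± 0.34 (adjusted p = 2.9e-06, quasi-likelihood test with Benjamini-Hochberg adjustment), Pck1 at 0.07 ± 0.27 (0.821), Cyp7a1 at 0.77 ± 0.25 (0.00379) and Fgf21 at -1.37 ± 0.40 (0.00131). The rise of Cyp7a1 is given without GC correction, which lowered the like rise in CR-night liver. Mitochondrial transcripts rose in 11 of 13 and macrophage markers fell in 13 of 16 (adjusted p = 0.998 for each with an estimated correlation).

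TR-night against AL isolated a 6 h window at the normal eating time. Of its 9626 called genes 4695 were higher and 4931 lower, but 0 passed on sums of regimen and letter by the same test (5303 at unadjusted p under 0.05, and 2 with GC correction). Cyp2b9 rose by 4.79 ± 0.63 log2 units (letters 6.84 and 4.13), Cyp2a4 by 1.97 ± 0.67 (but -0.13 on day 2 alone, letters 2.86 and 0.79) and Ccdc34 by 1.89 ± 0.31. The mitochondrial transcripts mt-Atp6 (3.26 ± 0.84), mt-Co2 (2.37 ± 1.04) and mt-Atp8 (8.85 ± 1.54) also rose and mt-Co3 fell (-7.30 ± 2.25), but these may share reads with nuclear copies or neighbours. Moxd1 fell by 2.89 ± 0.57, Rabac1 by 2.82 ± 0.29, Bri3 by 2.74 ± 0.31, Tspo by 2.73 ± 0.31 and Timm13 by 2.72 ± 0.27. Fasn was at -1.89 ± 0.34 (adjusted p = 4.9e-07, quasi-likelihood test with Benjamini-Hochberg adjustment), Fgf21 at -2.13 ± 0.43 (5.7e-06), Cyp7a1 at 0.89 ± 0.25 (9.2e-04) and Pck1 at -0.24 ± 0.27 (0.398). Here too the rise of Cyp7a1 is given without GC correction. Mitochondrial transcripts rose in 12 of 13 and fell in 1 (camera adjusted p = 0.0110, 0.976 with an estimated correlation). Macrophage markers, among them C1qc (-2.01 ± 0.21) and C1qb (-1.58 ± 0.20), fell in 13 of 16 (adjusted p = 0.0264, 0.976 with an estimated correlation). Across genes the folds against AL followed GC content with Spearman's rho of -0.806 in CR-night, -0.810 in TR-day and -0.817 in TR-night liver, and with GC correction 6677, 6973 and 7063 genes were called. Of the calls made without it, 5522, 5860 and 5961 were called again, and 4611, 4824 and 4859 of these kept their direction.

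CR against TR, over both feeding times, asked what less food adds to a feeding window. The test called 4109 genes higher and 3278 lower in CR liver, but within letter B alone 25 genes passed against 9332 within letter A, and on sums of regimen and letter 0 passed (445 at unadjusted p under 0.05). Male-biased genes fell in 16 of 18 and rose in 1 (median -0.63, -0.79 and -0.43 by letter, camera adjusted p = 1.1e-05, 0.865 with an estimated correlation). Ugt2b1 fell by 0.58 ± 0.09 (letters -0.91 and -0.30, adjusted p = 8.0e-07, quasi-likelihood test with Benjamini-Hochberg adjustment) and Cyp7b1 by 0.80 ± 0.14 (letters -1.34 and -0.34), with Mup17 at -2.86 ± 0.35. Cyp2b9 rose by 1.63 ± 0.31 (letters 2.15 and 1.02), and the metal handling genes Mt1 by 1.52 ± 0.32 (letters 2.95 and 0.21, and -0.0267 when refitted without letter A) and Slc39a4 by 1.32 ± 0.19 (letters 1.98 and 0.38). Genes of families with shared reads were also among the large differences, with Cyp2a4 (1.24 ± 0.44) and mt-Co3 (3.42 ± 1.36) higher and Mup14 (-2.34 ± 0.30), Mup11 (-1.92 ± 0.34), Mup1 (-1.70 ± 0.28), Mup12 (-1.65 ± 0.27) and mt-Nd4l (-1.70 ± 0.56) lower. Heat shock genes fell in 9 of 17 and rose in 1 (camera adjusted p = 0.0251, 0.865 with an estimated correlation), with Dnaja1 at -0.44 ± 0.10 (letters -0.87 and -0.08) and Hspd1 at -0.22 ± 0.06. Amino acid transport and mTORC1 genes rose in 10 of 18 and oxidative phosphorylation genes in 13 of 22 (3 fell). Macrophage markers rose in 14 of 16 and mitochondrial transcripts fell in 8 of 13. All 4 lists were lost with an estimated correlation (adjusted p = 0.865 for oxidative phosphorylation). Fasn (0.55 ± 0.23, letters 1.35 and -0.52), Pck1 (0.10 ± 0.19), Cyp7a1 (-0.36 ± 0.18) and Fgf21 (0.99 ± 0.32) had adjusted p of 0.0331, 0.651, 0.0647 and 0.00595 by the same test.

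Day against night feeding, over CR and TR together, asked which mean levels depend on when food comes. The test called 3757 genes higher and 2851 lower with day feeding, 752 within letter B and 8316 within letter A, and 20 passed on sums of regimen and letter. Fatty acid oxidation genes rose in 19 of 25 (median 0.39, 0.48 and 0.31 by letter, camera adjusted p = 5.3e-10, 0.0520 with an estimated correlation). Ehhadh stood at 0.56 ± 0.06 (letters 0.58 and 0.56) and Cyp4a10 at 1.29 ± 0.15 (letters 1.33 and 1.27). Lipolysis and lipid uptake genes rose in 12 of 17 (1 fell, camera adjusted p = 0.00167, 0.178 with an estimated correlation), including Cd36 (1.5 ± 0.19, letters 0.99 and 2.08) and Angptl4 (1.07 ± 0.16, letters 1.23 and 0.83). Xenobiotic genes rose in 13 of 21 (1 fell, camera adjusted p = 0.00167, 0.178 with an estimated correlation), with Cyp2b10 at 2.48 ± 0.35 (letters 2.12 and 2.91) and Abcc3 at 0.80 ± 0.09. Slc22a27 rose by 2.38 ± 0.28, Cyp4a14 by 1.90 ± 0.23 and Mt1 by 1.79 ± 0.32. Ntrk2 fell by 1.78 ± 0.27 (letters -2.16 and -1.44), Serpina12 by 1.71 ± 0.19 and Raet1d by 1.59 ± 0.17. With shared reads, Cyp2a22 (2.48 ± 0.28) and mt-Co3 (3.95 ± 1.29, but -2.35 when refitted without letter A) were higher and Serpina1e (-2.35 ± 0.24), Mup1 (-2.09 ± 0.28) and Mup12 (-1.99 ± 0.28) lower. Male-biased genes fell in 15 of 18 (camera adjusted p = 1.0e-05, 0.672 with an estimated correlation). Oxidative phosphorylation rose in 16 of 22 and fell in 2, macrophage markers rose in 11 and fell in 1, and mitochondrial transcripts rose in 2 and fell in 6 (adjusted p = 0.672, 0.850 and 0.674 with an estimated correlation). Pck1 (0.35 ± 0.19, adjusted p = 0.101), Fasn (0.53 ± 0.23, 0.0471, but 1.10 and -0.22 in letters A and B), Cyp7a1 (-0.37 ± 0.18, 0.0680) and Fgf21 (1.14 ± 0.32, 0.00180) completed this comparison.

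The interaction asked whether the day-night difference depended on the amount of food. It called 5477 of 11926 genes, 3283 higher and 2194 lower, but 1378 with GC correction. Within letter B and on sums of regimen and letter 0 passed by the same test (1536 and 98 at unadjusted p under 0.05), and DESeq2 on all libraries called 5743. Of the lists, macrophage markers rose in 11 of 16 and mitochondrial transcripts fell in 7 of 13 (adjusted p = 0.961 and 0.961 by camera with an estimated correlation), and no metabolic list passed. In pairs with no library in common, the genes lower with day feeding overlapped between CR and TR, 124 shared against 63.6 expected (odds ratio 3.39, p = 3.4e-18, 1-sided Fisher's exact test), as did the higher ones with 110 against 74.4 (odds ratio 2.11, p = 1.6e-07). Genes lower in CR than TR overlapped between day and night feeding in 19 against 10.2 expected (odds ratio 3.03, p = 0.00138), and those higher in 12 against 10.8 (p = 0.384). Fisher's test counts genes as independent, so these p-values do not measure spread between libraries.

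In BAT the mean levels asked how brown fat responded to restricted day feeding. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 301 of 10966 genes rose and 420 fell in CR-day against AL (n = 11 and 12 libraries, each group of a single letter). Ucp1, the uncoupling protein of brown fat (ENSMUSG00000031710.4, chromosome 8, 83290352 to 83298452, mm10), fell by 0.67 ± 0.14 log2 units, from 2700 ± 582 to 1721 ± 514 CPM (adjusted p = 0.00424; -1.06 and -0.35 on days 1 and 2). Of 25 thermogenesis genes 7 fell (9 over the list alone, median -0.18, camera adjusted p = 0.00886, 0.320 with an estimated correlation). They included Cox7a1 (-0.48 ± 0.09), Cox8b (-0.40 ± 0.10) and Gk (-1.14 ± 0.23). Cox7a1 and Cox8b are also expressed in skeletal muscle, whose 14 markers had a median of -1.62 in the same comparison. Of 20 fatty acid synthesis genes 6 rose and 1 fell (camera adjusted p = 0.0248, 0.579 with an estimated correlation), with Scd1 at 1.12 ± 0.16, Me1 at 0.89 ± 0.15, Fads1 at 0.76 ± 0.12 and Dgat2 at -0.44 ± 0.09. Cholesterol genes rose in 3 of 21 (4 over the list alone), and lipolysis genes fell in 2 of 18, Mgll (-0.41 ± 0.08) and Angptl4 (-0.93 ± 0.18). Fatty acid oxidation genes fell in 2 of 20, Hadhb (-0.30 ± 0.08) and Crat (-0.39 ± 0.12), with 7 down and 1 up over the list alone. The estimated correlation gave adjusted p = 0.579 for cholesterol, 0.579 for oxidation and 0.579 for lipolysis.

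Among the largest rises in BAT were Snhg11 by 1.56 ± 0.16 log2 units (1.75 and 1.4 on days 1 and 2), Unc119 by 1.53 ± 0.20, Prune2 by 1.44 ± 0.24, Atp10a by 1.38 ± 0.24 and Mgst2 by 1.34 ± 0.19. The largest falls were the imprinted gene Nnat by 3.09 ± 0.44 (-2.94 and -3.23 on days 1 and 2), Eef1a2 by 2.4 ± 0.58, Mypn by 2.21 ± 0.50, Scn4a by 2.19 ± 0.53, Klhl31 by 2.04 ± 0.58 and Ppp1r3a by 2.02 ± 0.61. Skeletal muscle markers moved with these falls: the median of 14 was -1.62, 2 fell (14 over the list alone, camera adjusted p = 0.107), and Mb fell by 1.99 ± 0.57. Macrophage markers rose in 2 of 13 and heat shock genes fell in 1 of 16 (camera adjusted p = 0.579 and 0.629 with an estimated correlation). Within day 1 alone 114 genes passed and within day 2 alone 5, and DESeq2 called 898.

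Comparing the 2 tissues asked whether levels responded to CR-day feeding in the same genes. Called genes overlapped in direction: 67 rose in both against 35.04 expected (odds ratio 2.27, p = 6.9e-08) and 52 fell in both against 20.3 (odds ratio 3.02, p = 2.3e-10, 1-sided Fisher's exact test over 10253 genes). As that test counts genes as independent, the p-values of these overlaps do not measure spread between libraries. Folds followed GC content in both tissues (Spearman's rho -0.600 in liver and -0.301 in BAT). With GC correction 44 rose in both against 24.99 expected (p = 1.5e-04) and 42 fell in both against 18.6 (p = 4.8e-07), and with at least 1.5-fold 5 and 3 were shared (p = 0.0214 and 0.0358). The response itself differed in 276 of 12799 genes, 121 higher and 155 lower in BAT than in liver, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The count was 1506 with liver libraries of the same letters as BAT, 521 without distant libraries, 36 on day 1 and 29 on day 2. Fatty acid oxidation genes had a lower response in BAT in 10 of 25 (16 over the list alone), such as Acadm (-0.86 ± 0.11, adjusted p = 4.0e-07), Hadhb (-0.72 ± 0.14, 6.2e-04) and Ehhadh (-0.84 ± 0.24, 0.0420). Fatty acid synthesis genes had a higher one in 5 of 20 (9 over the list alone), including Fads1 (1.01 ± 0.13, adjusted p = 4.1e-07), Me1 (1.04 ± 0.27, 0.0207) and Scd1 (1.18 ± 0.30, 0.0192). Vldlr (-2.60 ± 0.24, adjusted p = 4.0e-12) and Cd36 (-2.44 ± 0.46, 5.8e-04), which take up lipid, were picked after the values were seen.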

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

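The tests on other splits of the samples, on library size, on rhythms hidden by the AL letters, on larger amplitudes, on muscle and on wrong labels were written before their results were seen. The tests on the GC trend, the batch, AL depth and the letters compared were chosen after the result was seen.

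A difference between tissues singled out 3 results. The response to CR-day feeding differed between BAT and liver in the levels of 276 genes, where 1 of 30 splits of the libraries gave as many (highest other 10). It differed in the rhythms of 552 genes, where 1 of 30 did (highest other 38). Labels were exchanged within time point in BAT, and within time point and letter in liver. For levels and rhythms alike that 1 split was the real one, and the others gave far fewer. With 30 splits no smaller share is possible, so the splits by themselves do not exclude chance. They do not exclude the letters either, as each BAT group has a single letter. With liver libraries of the same letters as BAT the counts were 1506 for levels and 499 for rhythms, without distant libraries 521 and 772, on day 1 alone 36 and 19, and on day 2 alone 29 and 84. The median clock gene shift differed by 12.3 h (12.329, on a 24 h cycle where 12 h is the largest distance), and this was tested directly by bootstrap. A difference between amounts of food singled out the day-night difference of 5477 genes, higher in 3283 and lower in 2194. It came to 1378 genes with GC correction, and on sums of regimen and letter edgeR called 0 (98 at unadjusted p under 0.05).

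Clock genes of BAT and liver moved by different amounts under CR-day, with a difference of 12.329 h (95% interval 8.92 to 15.5 h). With the mean of the muscle list as a covariate in BAT it was 11.8 h (8.76 to 15.3 h), which argues against skeletal muscle in some BAT samples as the source. Without the 1 BAT library whose clock genes read more than 4 h from its label, CR-day at 32 h, it was 11.2 h (8.69 to 14.1 h), against that library alone as the source. Each reading was taken against the other libraries of the same group, so a time offset shared within a group would go unseen. The median distance of a reading from its label was 2.75 h in CR-day BAT and 0.5 h in AL BAT. With the same letters in liver as in BAT the difference was 12.7 h (9.21 to 16.2 h), against different letters. Day 1 alone gave 9.97 h (7.85 to 12.9 h) and day 2 alone 15.2 h (11.8 to 18.6 h). Leaving out each BAT library in turn gave 11.2 to 13.2 h. The BAT shift itself, over the same 7 genes, then ran from 0.615 to 2.61 h. It was 0.615, 1.06 and 0.962 h without CR-day at 32, 40 and 44 h, against 1.74 h without AL at 0 h. The bootstrap tested that the shifts differed, not why, so a different response of the tissue's own clock and a difference between animals or batches of the 2 tissues stay open.

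Letters of the same regimen differed in many liver genes, 9059 of them between the letters of CR-day. After GC and length correction 6481 genes still differed, which argues against a GC trend as the whole difference. With every library thinned to 5826600 counts 8399 did, against library size. CR-day letter A differed from AL letter B in 1316 of 12007 genes, fewer than from its own letter B. These 2 sets were singled out because they lie together on the main component, so this count restates their place. The labels name no batch, so a library batch that holds AL letter B and CR-day letter A and a biological difference between sets of mice cannot be told apart.

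That structure bears on the counts of liver calls. Of 30 splits with labels exchanged within time and letter, as many level changes came in 2 of 30 (real 2332, highest other 5814) for CR-day, so chance cannot be excluded there. For the other contrasts as many came in 1 of 30 (real 9442, highest other 6689) for CR-night, 1 of 30 (real 9584, highest other 6804) for TR-day, 1 of 30 (real 9626, highest other 2565) for TR-night. They came in 1 of 30 (real 7387, highest other 37) for CR against TR, 1 of 30 (real 6608, highest other 18) for day against night and 1 of 30 (real 5477, highest other 3981) for the interaction. In each of these the 1 was the real split, the smallest share that 30 splits allow. This by itself excludes neither chance nor the letters. Rhythm changes as many came in 2 of 30 (real 2613, highest other 2640) for CR-day, 4 of 30 (real 3, highest other 44) for CR-night, 1 of 30 (real 1944, highest other 1637) for TR-day. They came in 14 of 30 (real 1, highest other 2111) for TR-night, 2 of 30 (real 4055, highest other 4549) for CR-day against CR-night and 1 of 30 (real 3077, highest other 715) for TR-day against TR-night. With times permuted within a regimen, as many rhythmic genes came in 1 of 30 (real 1479, highest other 96) for AL, 4 of 30 (real 1950, highest other 4872) for CR-day. They came in 1 of 30 (real 4211, highest other 131) for CR-night, 1 of 30 (real 1843, highest other 3) for TR-day and 1 of 30 (real 3148, highest other 1) for TR-night. Chance cannot be excluded for the counts with a share of 0.05 or more. For the rhythmic genes of CR-day the permuted times also broke the balance of letters over time, so that test cannot decide. In BAT as many level changes came in 1 of 100 (real 721, highest other 200), and rhythm changes in 1 of 100 (real 1323, highest other 560). There too the 1 was the real split, the smallest share that 100 splits allow. This does not exclude the letters, since AL is all letter A and CR-day all letter B. As many rhythmic genes came in 1 of 100 (real 1148, highest other 49) for AL and 1 of 100 (real 1660, highest other 4) for CR-day.

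More genes passed the rhythm test in CR-night (4211) and TR-night (3148) than in AL liver (1479). With an intercept per regimen and letter and GC correction the counts were 6191, 5200 and 2995. CR-night then exceeded AL 2.07 times, against 2.85 times without these terms, which argues against the AL letters hiding rhythms as the whole source. AL libraries were the deeper ones, with a median total 1.21 times that of CR-night, against a lower depth of AL. Over 999 genes rhythmic in both day-fed groups the median amplitude was 1.36 times that of AL in CR-night (95% interval 1.19 to 1.5002, larger in 74.98% of genes) and 1.32 times in TR-night (1.16 to 1.48, larger in 77.2%). Counts passing within each group do not test a difference between groups. The direct test of a changed rhythm against AL passed 3 genes in CR-night and 1 in TR-night liver. Larger amplitudes with a night window may explain the counts, as a hypothesis.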

How the results depend on the processing

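The alternatives with GC correction, an intercept per regimen and letter, sums, AL letter B against CR-day letter A, limma on RPKM, and those without distant libraries were tests chosen after seeing the data, as was the clock shift with matched letters. Over all alternatives 79 of 82 clock shift values kept their sign and side of 0. All 18 values of the spread of shifts stayed inside their interval, and 11 of 12 overlaps kept their side of the threshold. The other, of genes higher in CR than TR between day and night feeding, gained it with GC correction (odds ratio 1.54, p = 0.0493). Counts stayed within 1.5 times for 79 of level changes (44 moved), 60 of rhythmic genes (32 moved), 58 of rhythm changes (37 moved), 10 of tissue differences (10 moved) and 12 of list tests (11 moved). For 188 named pairs of gene and comparison, 2110 of 2352 values kept sign and side, 175 lost and 28 gained the threshold and 39 changed sign. Relative log expression size factors moved no count and no named gene. Except where fewer libraries, a minimum fold or fewer samples were the construction, the cause was not tested.

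With a minimum of 1.5-fold in addition, level changes were 484 for CR-day, 5263 for CR-night, 5618 for TR-day, 5686 for TR-night, 1116 for CR against TR, 874 for day against night, 2548 for the interaction and 283 for BAT. On day 1 alone, with 6 time points, level changes were 519 for CR-day, 3593 for CR against TR, 877 for day against night, 536 for the interaction and 114 for BAT. Rhythmic genes were 292 for AL, 274 for CR-day, 1441 for CR-night, 238 for TR-day, 931 for TR-night, 81 for BAT AL and 72 for BAT CR-day. Rhythm changes were 735 for CR-day, 10 for CR-night, 437 for TR-day, 9 for TR-night, 1318 for CR-day against CR-night, 1032 for TR-day against TR-night and 81 for BAT. Tissue differences were 36 for levels and 19 for rhythms. The BAT clock shift was -0.704 h, reversed. Sign changed in log2 folds of Fgf21 (-0.83) in CR-day, Pck1 (0.0284) in CR-night, Pck1 (-0.0491) in TR-day, mt-Co3 (-0.47) in day against night.

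On day 2 alone, by the same test, level changes were 653 for CR-day, 1038 for the interaction and 5 for BAT. Rhythmic genes were 499 for AL, 926 for CR-day, 1497 for CR-night, 435 for TR-day, 1094 for TR-night, 85 for BAT AL and 191 for BAT CR-day. Rhythm changes were 967 for CR-day, 0 (313 at unadjusted p under 0.05) for CR-night, 742 for TR-day, 0 (232 at unadjusted p under 0.05) for TR-night, 2029 for CR-day against CR-night, 1423 for TR-day against TR-night and 203 for BAT. Tissue differences were 29 for levels and 84 for rhythms. The BAT clock shift was 2.87 h, its interval leaving out 0. Log2 folds reversed for Cyp7a1 (-0.19) in CR-day, Cyp2a4 (-0.13) in TR-night.

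Without replicate A or without replicate B, level changes ran from 7073 to 9089 for CR-day, 6235 to 9500 for CR-night, 25 to 9332 for CR against TR, 752 to 8316 for day against night and 0 to 7143 for the interaction. Rhythmic genes ran from 582 to 1801 for AL, 1124 to 1486 for CR-day, 2717 to 3317 for CR-night, 668 to 1284 for TR-day and 1558 to 2646 for TR-night. Rhythm changes ran from 0 to 0 for CR-night, 1177 to 1347 for TR-day and 0 to 0 for TR-night. The 0 of the interaction had 1536 genes at unadjusted p under 0.05, and the 0 of CR-night and TR-night rhythm changes 806 to 1222 and 261 to 1044. Log2 folds crossed 0 for Slc25a1 (-1.05 to 0.10), Fads2 (-1.65 to 0.17), Dhcr7 (-1.81 to 0.38), Nsdhl (-0.68 to 6.9e-04), Cyp3a25 (-0.0374 to 1.60), Insr (-0.0775 to 0.67), Igfbp3 (-0.0667 to 0.38), Igfals (-2.83 to 1.20), Onecut1 (-1.20 to 0.39), Cyp7a1 (-0.13 to 0.29), Fasn (-2.59 to 0.51), Fgf21 (-0.14 to 0.27) in CR-day. In CR-night they did for Pck1 (-0.44 to 0.0365). In CR against TR they did for Mt1 (-0.0267 to 2.81), Cyp7a1 (-0.83 to 0.15), Pck1 (-0.0143 to 0.21), Fasn (-0.46 to 1.37). In day against night they did for mt-Co3 (-2.35 to 5.42), Fasn (-0.25 to 1.08). Of the 2332 CR-day level calls 2108 were called again without replicate A (2098 in the same direction), but 1212 without replicate B, of which 472 kept their direction.

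The letters were also fitted as a replicate block, which gave 2220 level changes for CR-day and 1494 rhythmic genes for AL, within 1.5 times. With that replicate block, rhythm changes were 6 for CR-night. Sign changed in log2 folds of Fgf21 (-0.00303) in CR-day. With DESeq2, rhythm changes were 24 for CR-night and 7 for TR-night. Tissue differences were 416 for levels. Without the filter on low counts, rhythm changes were 85 for CR-night and 47 for TR-night. With 6 clock times as a factor, rhythmic genes were 652 for BAT AL. Rhythm changes were 1705 for CR-day, 1264 for TR-day and 700 for BAT. Tissue differences were 253 for rhythms. Log2 folds reversed for Pck1 (-0.11) in TR-day. With liver libraries of the letter of the BAT group, tissue differences were 1506 for levels. The TR-night clock shift was -0.659 h, its interval leaving out 0. With a peak to trough of at least 2-fold the circular mean shift of BAT genes was 8.90 h against 7.62 h.

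With GC and length correction, level changes were 4242 for CR against TR, 4068 for day against night and 1378 for the interaction. Rhythmic genes were 2319 for AL, 2945 for CR-day and 2779 for TR-day. Rhythm changes were 12 for CR-night, 2968 for TR-day and 3 for TR-night. Tissue differences were 496 for levels and 1132 for rhythms. Lists passing were 0 for TR-night. Sign changed in log2 folds of Cyp7a1 (-0.0785) in CR-day, Pck1 (0.26) in CR-night, Pck1 (0.26) in TR-night, Pck1 (-0.10) in CR against TR.

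With an intercept per regimen and letter, level changes were 4994 for CR-day. Rhythmic genes were 2438 for AL, 3115 for CR-day and 3286 for TR-day. Rhythm changes were 13 for CR-night and 3118 for TR-day. Log2 folds reversed for Fgf21 (-0.00787) in CR-day. With that intercept and GC correction, level changes were 4682 for CR against TR and 2155 for the interaction. Rhythmic genes were 2995 for AL, 3578 for CR-day, 3619 for TR-day and 5200 for TR-night. Rhythm changes were 4497 for CR-day, 22 for CR-night, 3632 for TR-day and 5023 for TR-day against TR-night. Sign changed in log2 folds of Cyp7a1 (-0.0459) in CR-day, Pck1 (0.26) in CR-night, Pck1 (0.23) in TR-night, Pck1 (-0.0969) in CR against TR.

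On sums of regimen and letter (2 per regimen), level changes were 26 for CR-day, 20 for CR-night, 25 for TR-day, 0 for TR-night, 0 for CR against TR, 20 for day against night and 0 for the interaction. Lists passing were 4 for TR-night and 7 for the interaction. Genes at unadjusted p under 0.05 were 5303 for TR-night, 445 for CR against TR and 98 for the interaction where none passed. On these sums with GC correction, level changes were 105 for CR-day, 56 for CR-night, 93 for TR-day, 2 for TR-night, 4 for CR against TR, 56 for day against night and 0 for the interaction. The interaction had 210 at unadjusted p under 0.05 there. Between AL letter B and CR-day letter A, level changes were 1316 for CR-day. Log2 folds reversed for Onecut1 (0.19), Cyp7a1 (-0.30) in CR-day.

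With limma on log2(RPKM + 0.1) of all 24 BAT libraries, level changes were 273 for BAT. Rhythmic genes were 1073 for BAT CR-day. Without distant libraries, rhythmic genes were 751 for BAT AL. Rhythm changes were 0 (757 at unadjusted p under 0.05) for CR-night. Tissue differences were 521 for levels. Sign changed in log2 folds of Fgf21 (-0.0255) in CR-day.

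With the correlation estimated from the residuals, camera passed 4 lists for CR-day and 0 for CR-night, TR-day, TR-night, CR against TR, day against night, the interaction and BAT, where lists at unadjusted p under 0.05 were 0, 0, 0, 0, 3, 0 and 1. With 11 and 12 libraries in BAT, 4 of the 67 smallest simulated level changes and 0 of 67 rhythms of 1.5-fold were recovered, and read depth was not varied in that simulation.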

Other observations

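Part of the heat shock genes carried a component with a 12 h period in day-fed liver. A 12 h component added to the model, in tests chosen after the result was seen, passed for 9 of 17 heat shock genes in CR-day liver among 86 genes in all (14 over the list alone, Fisher's exact p = 8.0e-16), with a median amplitude of 0.49 log2 units and a mean peak 4.49 h into each 12 h. In TR-day liver it passed for 9 of 17 among 83 genes (13 over the list alone, p = 5.7e-16, 0.44 log2 units, 4.72 h). It passed for 1 of 17 in AL (7 over the list alone, p = 0.00143), 1 in CR-night (5, p = 0.106) and 1 in TR-night liver (3, p = 0.0226), with median amplitudes of 0.20, 0.27 and 0.249. The enrichment by itself therefore does not set day-fed liver apart. Hsph1 had a 12 h amplitude of 1.09 in CR-day and 1.02 in TR-day liver, and Hspa8 0.80 and 0.87.

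The 12 h component describes the 9 and 9 members that passed. Peaks were not counted, and a single narrow or uneven daily peak can also give such a component, so 2 peaks a day are not shown. With even sampling a 12 h term is fitted apart from the 24 h wave. Its passing therefore does not by itself explain the weak 24 h wave, and the cause stays undecided for all members. A cue that day feeding does not shift, such as body temperature, could add to a cue that follows food, as a hypothesis. It needs heat shock amplitudes to fall more than clock amplitudes, and the ratio of these ratios was 0.668 in CR-day (95% interval 0.347 to 1.248) and 0.647 in TR-day liver (0.413 to 1.26). Both intervals hold 1, so this cue and its absence cannot be told apart with 17 and 19 genes.

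Lower male-biased and higher female-biased genes in CR-day liver could follow a weaker growth hormone signal. The growth hormone target list had a median log2 fold of -0.10 against AL (1 of 12 fell, 0.04 and -0.06 within letters A and B, camera adjusted p = 0.261), with members going both ways. Igfals went opposite ways in the letters (1.20 and -2.83), so the median pools opposite values and the 2 cannot be told apart. This test was chosen after the sex-biased lists were seen.

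Libraries far from their group, with a residual spread over 4 median absolute deviations above the median, were in liver AL at 12 h (letter B) and 0 h (A), TR-night at 0 h (A), CR-day at 44 and 24 h (B), TR-day at 20 h (B) and CR-night at 4 h (A), and in BAT AL at 20 and 28 h. Markers of sex and of other cells stood apart in 5 of these liver libraries. In AL at 12 h, CR-day at 24 and 44 h, CR-night at 4 h and TR-night at 0 h the mean log2 CPM of male-biased genes was 3.97, 2.87, 2.70, 2.97 and 4.39, against 7.79 in AL at 0 h and 6.05 in TR-day at 20 h. That of proliferation genes was 3.31, 2.64, 3.61, 3.17 and 3.98, against 0.573 and 0.535, and that of fibroblast markers 5.24, 5.61, 5.72, 5.16 and 5.17. CR-night at 0 h (A) had the same pattern (male-biased 2.91, proliferation 3.65, fibroblast 4.78) but was not distant and stays in the tests without distant libraries. In these tests Selenbp2 still fell in CR-day liver, by 4.09 log2 units. The median of male-biased genes was -1.38 in CR-day, -0.94 in CR-night, -0.97 in TR-day and -0.21 in TR-night liver. Clock genes read -8 h from the label in TR-day letter A at 0 h and -6.25 h at 44 h, and -6.25 h in BAT CR-day at 32 h. The median distance of a clock reading from its label was 0.5 h in AL, 1.62 h in CR-day, 0.5 h in CR-night, 1.38 h in TR-day and 0.625 h in TR-night liver, and 0.5 h in AL and 2.75 h in CR-day BAT. Exocrine pancreas, cold-induced and white fat lists were too small or too low in these samples to be tested by camera. Lists not described above did not pass in the comparisons with AL, such as bile acid synthesis in CR-day liver (median log2 fold -0.07, adjusted p = 0.401).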
